A study of Homo sapiens with 6 samples.

How the data were processed

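The series measured poly(A) RNA of human blood neutrophils in 3 groups of 2 libraries: unstimulated, PMA (25 nM, 3 h) and E. coli (multiplicity of infection 5, 3 h). Per the labels' protocols the cells were isolated by density centrifugation, and the libraries were made with a method that marks the strand. TopHat2, Picard and Cuffdiff with hg38 are named per the submitters' processing notes, without versions, order or settings. The gene annotation and any use of strand in counting are not given in the sources used here, so overlapping and antisense genes cannot be told apart with certainty.

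The deposited values are FPKM per gene and library with 1 added by the authors, as read from the values. The least value was 1 in every library, and 91.0% of the 2046 values between 10 and 11 carried 5 decimals, as a 6-digit number plus 1 would. The constant was taken off before use. A gene at 0 is called listed at 0, since an estimate can fail. The authors' group means were not used. Of 23967 genes, 1290 were at 0 in all libraries. No pair of libraries was identical.

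Depth was estimated from 329 olfactory receptor genes with a span of 900 to 1100 bp, whose values were whole multiples of a smallest step. Of the values up to 3 steps, 98.4% or more per library lay within 0.1 of a whole number. The value of 1 fragment per kb was 0.532, 0.569, 1.82, 1.85, 1.22 and 0.525 FPKM for unstimulated 1 and 2, PMA 1 and 2, and E. coli 1 and 2. On simulated olfactory receptor genes the largest error of this value was 2.16%. Any scaling between libraries by the authors would enter the estimate.

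Genes with a group mean of at least 1 FPKM in any group (19544) were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with a trended prior, all 6 libraries in 1 fit and a two-sided Benjamini-Hochberg adjusted p under 0.05. Fold changes are on that scale, which understates the change of low genes. Count models need counts and were not used. In 10 simulated sets for E. coli against unstimulated, on 19544 genes with 200 changed, limma recovered 5.80% of genes changed 4-fold, 73.4% of those changed 16-fold and 95.2% of those changed 64-fold. The false share of calls was 6.84%. A 4-fold shift of the chemokine list was found by camera in 10 of 10 sets. These sets gave all 6 libraries the same spread per gene and no effect of replicate number, unlike the data. The shares recovered may thus not hold here. LIF and NR4A1 rose by 7.03 and 6.91 log2 units with E. coli and were not called over all genes.

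The 30 gene lists were fixed before the data were examined, and 29 had at least 3 measured members. Members called were counted over all genes and adjusted over the list alone. Lists were tested with limma's camera, with a preset correlation of 0.01 and with an estimated one, over 87 tests. Each list's median fold change was also ranked among 10000 random lists of the same size matched on mean expression, in 20 bins, as a description. One-sided Fisher exact tests of called members, 174 in all, gave 0 with an adjusted p under 0.05. The lowest was for chemokines, with 1 member called and adjusted p = 0.16.

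Named genes followed a rule set before the data were examined. It took the 10 largest rises and 10 largest falls past the threshold with at least 5 FPKM in the higher group, and up to 4 called members per list. Since 1 gene passed per comparison, members called over their list alone were named as well, and more than 4 where a list had them. Genes named otherwise were chosen after their values were seen, as were the genes from the fit with the replicate block. XIST and Y-linked genes are not reported.

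The labels give each group replicates 1 and 2 without saying what a number shares. Deviations from the group mean of same-numbered libraries correlated across genes at 0.424 (unstimulated and PMA), 0.517 (unstimulated and E. coli) and 0.456 (PMA and E. coli). All lay above 0.1, and the numbers were treated as pairing the libraries. With 2 libraries per group these are only 3 separate values. Mean FPKM of olfactory receptor genes was also higher in replicate 1 of each group. It was 0.700 against 0.249 in unstimulated, 2.63 against 0.901 in PMA and 0.903 against 0.0866 in E. coli libraries. The correlations thus cannot show that a number stands for a shared donor or day. The calls of both fits had been seen by the time the bound of 0.1 was applied. The fit without the block thus remained the main one, as planned. Blocked values stand beside it where they change a count adjusted over a list alone.

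For the responses compared, 100 sets of unchanged groups were simulated with each gene's fitted spread. The alternatives set before the data were examined were other thresholds, filters, a pseudocount of 0.1, equal medians, leaving out each library, and the replicate block. A further 5 settings per comparison were added after the data were seen. Figures were drawn with matplotlib 3.10.9.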

Results

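RNA was sequenced from human blood neutrophils that were left unstimulated, treated for 3 h with phorbol myristate acetate (PMA, 25 nM), or exposed for 3 h to E. coli of a K1 strain at a multiplicity of infection of 5. PMA is a phorbol ester that activates protein kinase C directly, without a surface receptor. No incubation time is given for the unstimulated cells. An effect of time in culture thus cannot be told apart from that of either stimulus. Each of the 3 groups held 2 libraries, 6 in all, and the deposited table gave an FPKM value per library for 23967 genes. The labels do not say whether the libraries of a group came from separate donors or cultures, so p-values measure the spread between these samples, which may be technical. In 329 short olfactory receptor genes the values fell on steps, which gave the worth of 1 fragment and an estimated depth. That depth was 1880000 and 1760000 fragments for the unstimulated libraries, 548000 and 539000 for PMA, and 822000 and 1900000 for E. coli. These are shallow libraries, and low values rest on few fragments.

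PMA replicate 1 stood apart from the other libraries. Across 6279 genes with a group mean of at least 10 FPKM, its log2 values correlated with the others at r between 0.123 and 0.429. The unstimulated pair reached r = 0.922 and the E. coli pair r = 0.792. These correlations are across genes, which are not independent replicates. Its 99th percentile was 33.7 FPKM, against 244 FPKM for PMA replicate 2 at about the same estimated depth. Olfactory receptor genes, which are not known to be active in neutrophils, averaged 2.63 FPKM in PMA replicate 1 and between 0.0866 and 0.903 FPKM in the other 5 libraries. FPKM values of PMA libraries are therefore given per library.

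**Figure D1:**
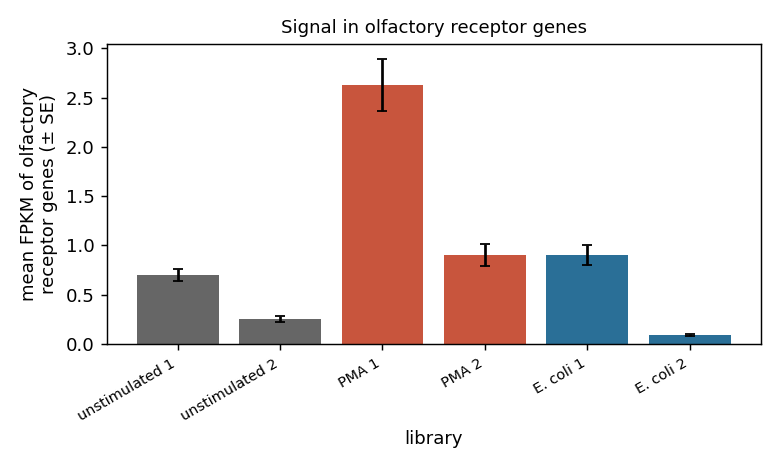
Mean FPKM of 379 olfactory receptor genes in each library (bars, axis from 0), with the standard error over genes; colours mark the group. PMA replicate 1 stands at 2.63 FPKM and the other 5 libraries at 0.903 FPKM or less.

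The E. coli comparison asked which transcripts differ after an encounter with bacteria. Of the immediate early genes, the transcription factors and regulators induced within minutes to hours of a stimulus, 7 of 29 rose when p-values were adjusted over the list alone. In 24 of the 29 both E. coli libraries lay above both unstimulated libraries, where chance gives 16.7% of genes and all genes tested gave 8.15%. Among the 7 were the orphan nuclear receptor NR4A1 (378 ± 187 FPKM, SD, n = 2, against 1.99 ± 0.718 FPKM) and the zinc finger factor EGR2 (271 ± 49.4 against 3.92 ± 2.87 FPKM). Of the chemokines, the secreted proteins that attract leukocytes, 5 of 18 rose over their list alone, and 5 of 20 inflammatory cytokines did. The monocyte attractant CCL2 was listed at 0 in both unstimulated libraries and at 45.8 and 31.1 FPKM in the E. coli libraries.

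Over all 19544 genes tested with limma, 1 gene rose and 0 fell at an adjusted p under 0.05. The 393 genes with an unadjusted p under 0.05 were fewer than chance alone would give. All groups share 1 estimate of the spread, so the PMA pair, with r = 0.429 between its libraries, enters this test too. A low count is thus no evidence that few genes changed. The gene called was CCL3L1, a copy of the macrophage inflammatory protein gene CCL3, with limma adjusted p = 0.0238. It was listed at 0 in both unstimulated libraries and at 221 and 133 FPKM in the E. coli libraries. Its deposited locus lies on an alternate scaffold of chromosome 17, and it is nearly identical to CCL3L3, so its share of the fragments is uncertain. The call was lost when any 1 of the 6 libraries was left out, with 0 genes called each time. With the planned minimum of 5 FPKM, 8 genes rose and 0 fell among 9938. They included NR4A1, NR4A2, NR4A3, EGR2, CCL2 and the lactate receptor gene HCAR1, which had 31.9 ± 10.4 FPKM against 0.623 ± 0.0301 FPKM (SD, n = 2). HCAR1 was named after its values were seen. On hg38 the deposited locus of NR4A1 is chromosome 12, 52022832 to 52059507, and that of EGR2 is chromosome 10, 62811996 to 62819167.

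Within the immediate early genes, 7 of 29 rose and 0 fell when p-values were adjusted over the list alone, and 0 over all genes. The 7 were NR4A1, NR4A2, NR4A3, EGR1, EGR2, EGR3 and FOSB. NR4A1 rose by 6.91 ± 1.02 (SE) on the log2(FPKM + 1) scale, NR4A3 by 6.86 ± 1.00, NR4A2 by 6.32 ± 0.87 and EGR2 by 5.91 ± 0.84, each with limma adjusted p = 0.00123 over the list. FOSB, a partner in the AP-1 dimer, stood at 363 ± 47.1 against 12.9 ± 4.07 FPKM (SD, n = 2). The list's median log2 fold change was 1.91, and limma's camera gave adjusted p = 4.99e-27 with a preset correlation but adjusted p = 0.766 with an estimated correlation. The count of 7 for immediate early genes became 4 without unstimulated replicate 1, 0 without unstimulated replicate 2, 0 without E. coli replicate 1, and 16 without either PMA library. With the replicate number as a block it was 13.

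Within the chemokines, 5 of 18 rose and 0 fell when adjusted over the list alone, and 1 rose over all genes. These were CCL3L1, CCL2, CXCL2, CCL4L2 and CCL20. With the replicate block 7 rose over the list alone, CCL3 and CCL4 being added. CXCL2, a neutrophil attractant, stood at 207 ± 34.9 against 2.98 ± 1.69 FPKM (SD, n = 2), and CCL4L2, a near-identical copy of CCL4, at 302 ± 118 against 14.6 ± 5.20 FPKM. The chemokine median was 1.65 log2 units, with camera adjusted p = 1.06e-19, and adjusted p = 0.766 with an estimated correlation. The count for chemokines was 2 without either unstimulated library and 2 without E. coli replicate 1. CCL2 and CCL3L1 kept their list call in 6 of the 6 fits that left out a library.

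Within the inflammatory cytokines, 5 of 20 rose and 0 fell when adjusted over the list alone, and 0 over all genes. They were LIF and OSM, of the interleukin-6 family, IL1A, and the growth factors HBEGF and AREG, which act on the epidermal growth factor receptor. LIF stood at 295 ± 104 against 1.21 ± 0.229 FPKM (SD, n = 2) and OSM at 598 ± 277 against 9.93 ± 5.10 FPKM. IL1B, which did not pass in the main fit, had 637 and 365 FPKM in the E. coli libraries and 52.2 and 95.6 FPKM in the unstimulated ones. With the replicate block IL1B and TNF rose over the list alone (limma adjusted p = 0.0424 for each). Camera gave adjusted p = 5.91e-09 for inflammatory cytokines, and adjusted p = 0.766 with an estimated correlation. The count for inflammatory cytokines fell to 0 without either unstimulated library or without E. coli replicate 1, and was 7 with the replicate block. LIF and HBEGF were also the 2 of 17 members called in the ERK pathway feedback list, which held 0 without any 1 unstimulated or E. coli library.

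**Figure D2:**
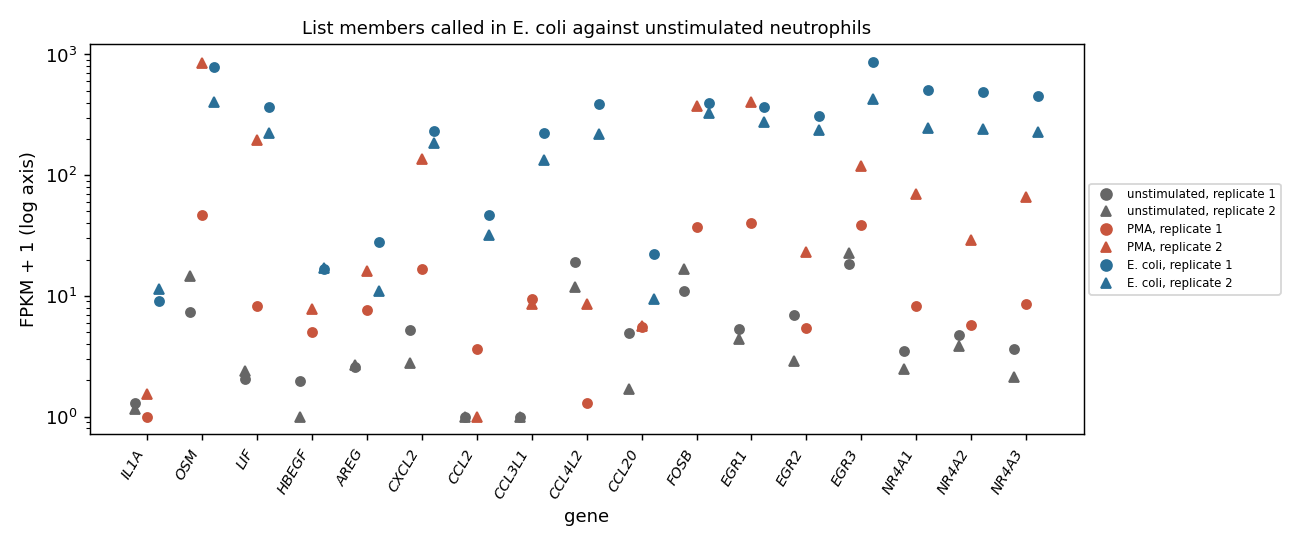
FPKM + 1 per library (log axis) for the members of the immediate early, chemokine and cytokine lists that passed limma adjusted over their list in E. coli against unstimulated neutrophils. Circles are replicate 1 and triangles replicate 2; for NR4A1 the E. coli libraries stand at 510 and 246 FPKM and the unstimulated ones at 2.50 and 1.48 FPKM.

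Heat shock and unfolded protein response genes had a median log2 fold change of 1.04 in E. coli against unstimulated neutrophils, with camera adjusted p = 1.17e-08, and adjusted p = 0.766 with an estimated correlation. None of the 23 members passed alone, over the list or over all genes, and 4 rose with the replicate block adjusted over the list alone. Adjusted in that way, 5 heat shock members rose without PMA replicate 1, 5 without PMA replicate 2, and 4 at 5 FPKM or more.

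Specific and gelatinase granule proteins had a median of 0.27 in E. coli against unstimulated neutrophils (camera adjusted p = 0.0207, and adjusted p = 0.766 with an estimated correlation). Of their 20 members 1 rose over the list alone, the pentraxin PTX3, at 20.5 ± 3.99 against 0.996 ± 0.0482 FPKM (SD, n = 2). PTX3 kept that call in 2 of 6 fits that left out a library, and lost it without any 1 unstimulated or E. coli library. Metallothioneins, small metal-binding proteins, had a median of -1.13 (camera adjusted p = 0.00627, and adjusted p = 0.766 with an estimated correlation), with 0 of 11 members passing alone. Housekeeping genes had a median of 0.34 (camera adjusted p = 0.0407, 0.0605 with the replicate block, and adjusted p = 0.766 with an estimated correlation). With the replicate block, the JAK-STAT feedback list held 1 member higher over the list alone, and the apoptosis regulators and housekeeping genes each 1 higher and 1 lower, where none passed without it. Among random lists matched on mean expression, the 8 lists past camera in this comparison stood at percentile 98.12 or more, except metallothioneins at 0.

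The PMA comparison asked which transcripts differ between cells after 3 h with PMA and unstimulated cells. When p-values were adjusted over each list alone, 3 of 23 heat shock and unfolded protein response genes and 3 of 18 chemokines rose, and 4 of 30 pattern recognition and inflammasome genes fell. None of them passed over all genes without the replicate block. With it, 4 heat shock genes and 2 chemokines rose over all genes. In that fit 1 chemokine and 6 pattern recognition genes fell. The inducible chaperone HSPA1B had 142 and 335 FPKM in the PMA libraries against 11.2 and 10.99 FPKM in the unstimulated ones. The lipopolysaccharide receptor TLR4 had 7.44 and 20.9 FPKM against 110 and 162 FPKM. The median log2 fold change of all genes was 0.50, -0.70 among genes with at least 5 FPKM and -1.38 among those with at least 10 FPKM. The median of all genes was 0.07 without PMA replicate 1.

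Over all genes limma called 1 gene higher and 0 lower, while 3831 had an unadjusted p under 0.05. The gene was RNU6-28P, a U6 small nuclear RNA pseudogene, with adjusted p = 0.00255. It was listed at 0 in the 4 libraries without PMA and at 659 and 670 FPKM in the PMA libraries. These values were 361.2 and 361.6 times the value of 1 fragment per kb. Other small RNA genes, named after their values were seen, also took repeated multiples. SNAR-E stood at 196.4, 196.6 and 197.0 in 3 libraries and at 0 in the others, and RNU6-31P at 306.4, 613.1 and 613.3 in 3 libraries and at 0 in the others. The call may therefore rest on an equal and very small number of fragments in both PMA libraries. The deposited locus of RNU6-28P is chromosome 22, 31439359 to 31489888, and the transcript length behind its values is not given. With the replicate number as a block, limma called 291 genes higher and 1123 lower. By the rule for named genes applied to that fit, a choice made after the values were seen, the largest rises included PHLDA2, EGR1, SOCS3, HSPH1, HSPA1B and EDN1. SOCS3, an inhibitor of cytokine signalling, had 32.2 and 623 FPKM against 5.10 and 8.29 FPKM, and PHLDA2 had 9.99 and 293 FPKM. The largest falls included CEBPA, a myeloid transcription factor, at 0.589 and 2.998 FPKM against 46.9 and 70.8 FPKM, and HIST1H4D, listed at 0 in both PMA libraries against 38.3 and 43.7 FPKM. Several of these genes moved alike with E. coli, where HSPA1B had 182 and 97.2 FPKM, SOCS3 207 and 276 FPKM, and CEBPA 2.76 and 8.15 FPKM. In the same libraries PHLDA2 had 0 and 10.9 FPKM, and HIST1H4D 35.1 and 47.9 FPKM, near its unstimulated values. With the planned minimum of 5 FPKM, 1 gene was higher and 15 were lower. The count was 339 without PMA replicate 2 and 0 without any other single library.

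Heat shock and unfolded protein response genes held 3 of 23 members that rose and 0 that fell when adjusted over the list alone, and 0 over all genes. HSPA1B rose by 4.18 ± 0.86 (SE, log2), with limma adjusted p = 0.0221 over the list, HSPE1 by 3.77 ± 0.82 and HSPH1 by 4.21 ± 1.01. HSPA1B is nearly identical to HSPA1A, so the split of fragments between them is uncertain. Camera gave adjusted p = 0.254 for heat shock and unfolded protein response genes, and 7.46e-04 without PMA replicate 1. The count of 3 rose to 8 without PMA replicate 1, and was 1 higher and 4 lower without PMA replicate 2. It was 0 when an unstimulated or E. coli library was left out, and 6 higher and 3 lower with the replicate block. In both PMA libraries 11 of the 23 members lay above both unstimulated libraries and 5 below, where 36.7% and 25.3% of all genes did.

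Among the chemokines 3 of 18 rose, CCL3L1, CXCL2 and CXCL5, and 1 fell, CXCL6, when adjusted over the list alone. Over all genes 0 passed. With the replicate block 4 rose over the list alone, CCL5 being added, and 1 fell. CCL3L1 had 8.42 and 7.50 FPKM against 0 in both unstimulated libraries. Its PMA values stand for 4.6 and 4.0 fragments per kb, so its call rests on few fragments. CXCL5, low as well, had 4.38 and 7.01 FPKM against 0.365 and 0.587 FPKM. CXCL6 had 1.97 and 1.00 FPKM against 14.0 and 11.7 FPKM. The chemokine counts were 0 without either unstimulated library, 4 higher and 1 lower without PMA replicate 1, and 1 higher and 2 lower without PMA replicate 2. CCL3L1 kept its call in 4 of the 6 fits that left out a library, CXCL5 and CXCL6 in 3 each, and CXCL2 in 1. Immediate early genes had a median of 1.32 with camera adjusted p = 0.0467, which was 0.0667 with the replicate block and 2.32e-12 without PMA replicate 1. With an estimated correlation the adjusted p was 0.850. None of the 29 immediate early genes passed alone, while 17 did without PMA replicate 1 and 2 with the replicate block. EGR1 had 39.5 and 405 FPKM in the PMA libraries against 4.27 and 3.35 FPKM. ERK pathway feedback genes, which restrain that kinase cascade, had a median of 1.16 and camera adjusted p = 0.00848, and adjusted p = 0.766 with an estimated correlation. Over the list alone 0 of them passed, and 7 rose and 1 fell with the replicate block. The chemokine list did not pass camera (adjusted p = 0.254, and adjusted p = 0.850 with an estimated correlation). Ranked among random lists matched on mean expression, heat shock and immediate early genes stood at percentile 100 and chemokines at 99.95. Inflammatory cytokines stood at 99.86, ERK pathway feedback at 98.73, and housekeeping genes, with a median of -0.03, at 98.24. These ranks only describe the lists, since random lists ignore correlation between members.

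Pattern recognition and inflammasome genes held 4 of 30 members that fell and 0 that rose when adjusted over the list alone, and 0 over all genes. All 4 were Toll-like receptors, namely TLR1, TLR4, TLR6 and TLR8. TLR1 fell by 3.49 ± 0.74 (SE, log2; limma adjusted p = 0.046 over the list), from 118 and 136 to 10.3 and 10.4 FPKM. Both PMA libraries lay below both unstimulated ones in 21 of the 30 members, against a chance share of 16.7% and a share of 25.3% over all genes. The list's median of -1.63 stood at percentile 14.77 among random lists matched on mean expression. All genes with at least 5 FPKM had a median of -0.70, and those with at least 10 FPKM a median of -1.38. The fall of this list was thus largely shared by abundant genes of any kind. Camera gave adjusted p = 8.92e-08 for pattern recognition and inflammasome genes, 0.00171 without PMA replicate 1, and 0.766 with an estimated correlation. The count was 0 without PMA replicate 1, 14 without PMA replicate 2, and 0 without any other library. With the replicate block it was 10. Counts adjusted over the list alone moved by more than 1.5 times with the replicate block in 20 of 29 lists for PMA against unstimulated, 5 of 29 for E. coli against unstimulated and 19 of 29 for E. coli against PMA.

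The list of the respiratory chain, nuclear encoded, had a median of -1.04 over 84 members (camera adjusted p = 2.25e-08, and 4.74e-06 without PMA replicate 1). With an estimated correlation the adjusted p was 0.766, and among matched random lists the median stood at percentile 3.06. ATP5H and NDUFB10 fell when adjusted over the list alone, 0 members did without PMA replicate 1 or without either unstimulated library, 8 without PMA replicate 2, and 24 with the replicate block. ATP5H was listed at 0 in both PMA libraries against 33.2 and 25.6 FPKM. Interferon-stimulated genes, neutrophil surface receptors, cytosolic ribosomal proteins, NF-kappaB components, NADPH oxidase, apoptosis regulators, glycolysis, NRF2 and chromosome architecture genes also had negative medians, between -0.81 and -1.77. Each passed camera with all libraries, and none of these 9 lists passed without PMA replicate 1 or with an estimated correlation, where the adjusted p was 0.766 for each. Among random lists matched on mean expression none of the 9 was low. NF-kappaB components stood at percentile 98.95, against camera's direction, NRF2 at 92.07, interferon-stimulated genes at 86.74, glycolysis at 78.44, chromosome architecture at 62.21, apoptosis regulators at 58.15, NADPH oxidase at 51.86, ribosomal proteins at 51.27 and neutrophil surface receptors at 27.65. Among the 9 lists, RAP1A of the NADPH oxidase list and the catalase gene CAT fell when adjusted over their list, and neither did so without PMA replicate 1. RAP1A kept its call in 1 of 6 fits that left out a library and CAT in 3. CAT had 3.41 and 6.94 FPKM against 88.9 and 106 FPKM. Basophil markers had a positive median of 1.33 over 5 members (camera adjusted p = 0.045, 0.0527 with the replicate block, and adjusted p = 0.766 with an estimated correlation) and did not pass without PMA replicate 1.

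With the replicate block, further counts adjusted over the list alone changed for PMA against unstimulated. Chromosome architecture then held 3 members higher and 11 lower, apoptosis regulators 1 and 8, glycolysis 1 and 7, inflammatory cytokines 7 and 1, interferon-stimulated genes 0 and 7, and NF-kappaB components 0 and 5. NRF2 and oxidative stress genes held 0 higher and 4 lower, NADPH oxidase 0 and 3, neutrophil surface receptors 0 and 3, JAK-STAT feedback 2 and 3, and cytosolic ribosomal proteins 0 and 2. Basophil markers held 2 higher and 0 lower, platelet markers 2 and 1, monocyte markers 0 and 1, and specific and gelatinase granule proteins 0 and 1. Without the block these counts were 0, except 1 lower each for the NRF2 and NADPH oxidase lists.

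**Figure D3:**
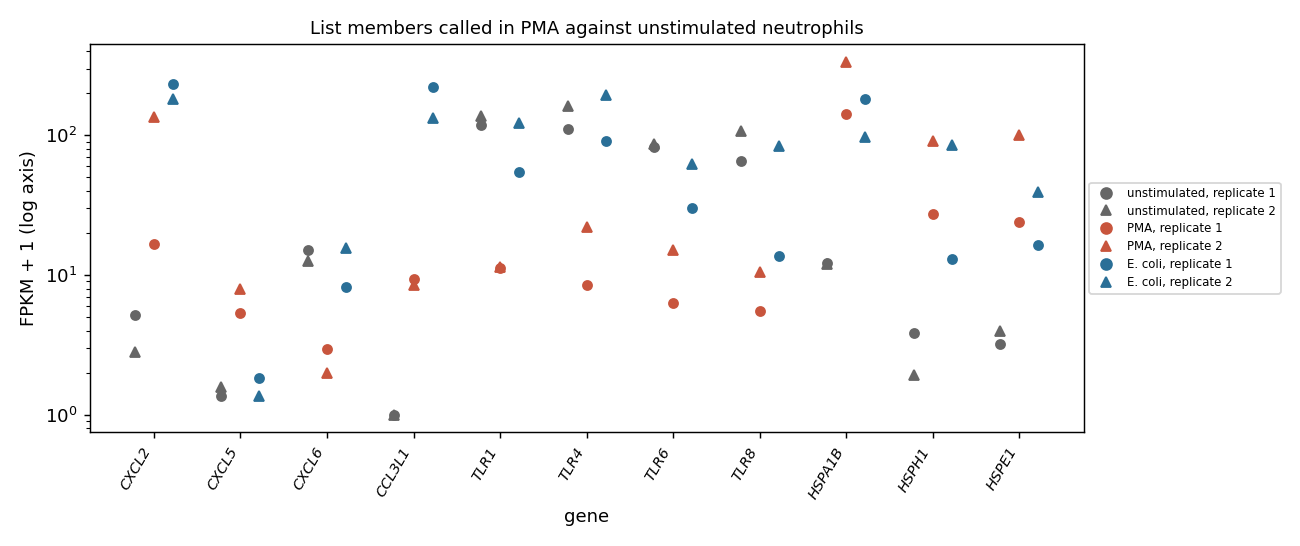
FPKM + 1 per library (log axis) for the members of the heat shock, chemokine and pattern recognition lists that passed limma adjusted over their list in PMA against unstimulated neutrophils. Circles are replicate 1 and triangles replicate 2; TLR4 stands at 7.44 and 20.9 FPKM with PMA and at 110 and 162 FPKM without stimulus.

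The direct comparison asked where the 2 stimuli differ. When adjusted over each list alone, 5 of 18 chemokines were higher with E. coli than with PMA and 1 was lower, and 4 of 29 immediate early genes were higher. None of them passed over all genes. CCL4L2 had 385 and 218 FPKM with E. coli against 0.294 and 7.50 FPKM with PMA. IL1B had 637 and 365 FPKM against 22.1 and 54.0 FPKM. Over all genes limma called 0 genes higher with E. coli and 1 lower, RNU6-28P, at adjusted p = 0.00255, while 3385 had an unadjusted p under 0.05. The RNU6-28P call may rest on very few fragments, as in PMA against unstimulated. The replicate block added HIST1H4D as 1 higher gene (adjusted p = 0.0152). With the planned minimum of 5 FPKM, 6 genes were higher and 1 was lower. The count was 913 without PMA replicate 2 and 0 without any other single library.

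Of the chemokines, 5 of 18 were higher with E. coli, CCL4L2, CCL3L1, CCL2, CCL3 and CXCL6, and 1 was lower, CXCL5, when adjusted over the list alone. CCL2, CCL3L1 and CCL4L2 kept that call in 6 of 6 fits that left out a library. The chemokine count was 3 higher and 0 lower without either unstimulated library, PMA replicate 1 or E. coli replicate 2, 4 and 2 without E. coli replicate 1, and 8 and 1 without PMA replicate 2. Of the immediate early genes, 4 of 29 were higher with E. coli, namely EGR2, NR4A1, NR4A2 and NR4A3, and 0 were lower. NR4A2 differed by 4.72 ± 0.87 (SE, log2; limma adjusted p = 0.0104 over the list). The count for immediate early genes was 0 without any 1 library except PMA replicate 2, without which it was 21 higher and 1 lower. With the replicate block it was 6 higher and 2 lower. Of the 20 inflammatory cytokines, IL1A and IL1B were higher and EBI3 lower over the list alone. This count for inflammatory cytokines was 0 without either unstimulated library or E. coli replicate 2, 0 higher and 1 lower without PMA replicate 1, 7 and 2 without PMA replicate 2, and 1 and 2 without E. coli replicate 1. IL1B kept its call in 1 of these 6 fits, IL1A and EBI3 in 2 each, and 7 were higher and 5 lower with the replicate block. EBI3, a subunit of interleukins 27 and 35, had 9.20 and 6.24 FPKM with PMA against 1.03 and 0 FPKM. With 1 fragment per kb worth 1.82 and 1.85 FPKM in PMA replicates 1 and 2, the EBI3 call rests on few fragments. PMAIP1, a pro-apoptotic BCL2 family gene, was higher with E. coli over its list alone, at 209 and 217 against 11.6 and 25.2 FPKM. PMAIP1 kept that call in 1 of 6 fits that left out a library, the fit without PMA replicate 2.

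In E. coli against PMA camera passed 17 lists, 5 without PMA replicate 1, and 0 with an estimated correlation, where no adjusted p was below 0.766. With the replicate block 15 passed, lipid mediators (adjusted p = 0.0543) and housekeeping genes (adjusted p = 0.0521) no longer being among them. The 5 left without PMA replicate 1 were chemokines, pattern recognition, neutrophil surface receptors, ribosomal proteins and the respiratory chain, each higher with E. coli. These 5 stood at percentiles 100, 83.46, 99.43, 95.26 and 95.22 among random lists matched on mean expression. Other lists that camera called higher with E. coli lay low among matched lists, namely NRF2 at percentile 0.12, immediate early genes at 0.33, housekeeping genes at 1.24, interferon-stimulated genes at 2.77 and apoptosis regulators at 12.1. Specific and gelatinase granule proteins stood at 99.77, and NF-kappaB components, NADPH oxidase, chromosome architecture, glycolysis and lipid mediators between 33.24 and 57.63. Basophil markers, called lower, stood at 1.55.

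Adjusted over the list alone, the replicate block gave, for E. coli against PMA, 21 higher and 1 lower for the respiratory chain, 11 and 0 for pattern recognition, 7 and 0 for NF-kappaB components, and 7 and 0 for specific and gelatinase granule proteins. It gave 5 and 1 for glycolysis, 2 and 1 for apoptosis regulators, 1 and 1 for heat shock, and 2 and 0 each for JAK-STAT feedback, NADPH oxidase, NRF2 and neutrophil surface receptors. Basophil markers had 0 higher and 4 lower, ribosomal proteins and monocyte markers 1 and 0 each, and ERK pathway feedback, azurophil granule proteins and platelet markers 0 and 1 each. Without the block these counts were 0, except 1 higher each for the respiratory chain and the apoptosis regulators. For chemokines the block gave 6 higher and 1 lower, adding CCL4 to the 5 higher without it.

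The responses to E. coli and PMA were also compared gene by gene. Across 19544 genes the log2 fold changes against the unstimulated libraries correlated at Pearson r = 0.348 and Spearman rho = 0.317, and genes are not independent replicates. Unchanged groups simulated against the same control libraries gave a mean r of 0.501 and rho of 0.478, above the observed values. The simulation gave each gene 1 spread in all libraries, unlike the data. The lower r thus does not show that the responses are less alike than the shared controls alone give. The covariance was 0.316 against a simulated 0.319, a difference of -0.00314. With the spread of the fit with the replicate block, the simulated covariance was 0.180 and the difference 0.136. The correlation was -0.205 without E. coli replicate 1 and 0.612 without E. coli replicate 2. With equal medians it was 0.504, and with a pseudocount of 0.1 it was 0.218. No gene was called in both comparisons in the same direction, where independent lists would share 5.12e-05 genes. With the replicate block the shared gene was CCL3L1, 1 gene against 0.0149 for independent lists. Its PMA values, 4.6 and 4.0 fragments per kb, rest on few fragments. At 10 FPKM or more, a setting added after the data were seen, 10 genes were called higher and 3 lower in both, against 0.143 and 0.265 for independent lists. Part of any overlap may come from the shared controls. With 1 control library for each response, the PMA response of replicate 1 and the E. coli response of replicate 2 correlated at r = -0.145, and the PMA response of replicate 2 and the E. coli response of replicate 1 at r = 0.440. Within replicate 1, with 1 control library in common, r was 0.443, and within replicate 2 it was 0.148. For the same stimulus and separate controls, the PMA responses of replicates 1 and 2 correlated at r = 0.570 and the E. coli responses at r = 0.228, so the E. coli pair lay below the r of 0.440 between stimuli.

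Markers of other cell types were measured with the same tests. Eosinophil markers held 2 of 13 that fell with PMA when adjusted over the list alone, CCR3 and RNASE2, while 4 members lay above both unstimulated libraries in both PMA libraries and 3 below. The eosinophil median was 0.20 and the mean -0.28, and camera, with direction down, gave adjusted p = 0.521. Against random lists matched on mean expression that median stood low, at percentile 0.52, and the list's median for E. coli against PMA stood at 97.57. CCR3 kept its call in 4 of 6 fits that left out a library, the fit without PMA replicate 1 among them, and RNASE2 in 2, that fit not among them. Both lost it without either unstimulated library. CCR3 had 4.73 and 6.73 FPKM with PMA against 59.8 and 52.8 FPKM, and 24.0 and 30.0 FPKM with E. coli. In E. coli against PMA both were higher over the list alone (limma adjusted p = 0.0484 for CCR3 and 0.0227 for RNASE2), and each kept that call in 1 of 6 fits that left out a library. Neither eosinophil, monocyte, T and NK cell, B cell, platelet nor erythroid markers passed camera in any of the 3 comparisons with all libraries. Azurophil granule proteins, JAK-STAT feedback genes and, against unstimulated, lipid mediators did not pass either. Of the metallothionein list the zinc exporter SLC30A1 fell with PMA, from 15.4 and 18.7 to 0.789 and 1.60 FPKM, over the list alone. SLC30A1 kept that call in 2 of 6 fits that left out a library, the fit without PMA replicate 1 not among them. No member of the mitochondrially encoded list was in the table.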

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

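The counts of called genes were unstable. In all, 19 settings were run per comparison, 14 planned and 5 chosen after the data were seen, and the cause of a change was not tested unless stated. For PMA against unstimulated (1 gene), the count was 80 with no filter, 16 at 5 FPKM or more, 2 with a pseudocount of 0.1, 4 with equal medians and 1414 with the replicate block. Added settings gave 444 at 10 FPKM or more, 11 with quantile scaling, 3699 and 3251 with the replicate block at 5 and 10 FPKM or more, and 0 among genes up to 250 fragments per kb. That last filter takes out the genes called in the main fit. RNU6-28P stood at 361.2 fragments per kb in PMA replicate 1 and CCL3L1 at 253.5 in E. coli replicate 2. The loss of their calls under it was thus fixed in advance in each comparison. Leaving out a library gave 0 to 339. For E. coli against unstimulated (1 gene), it was 0 at an adjusted p under 0.01, 23 with no filter and 8 at 5 FPKM or more. CCL3L1, the gene called in the main fit, was not among those called with quantile scaling. Added settings gave 36, 9, 88, 152 and 0 in the same order, and leaving out a library gave 0 each time. For E. coli against PMA (1 gene), it was 65 with no filter, 7 at 5 FPKM or more, 2 with a pseudocount of 0.1, 2 with equal medians and 2 with the replicate block. Added settings gave 40, 0, 2339, 2379 and 0, and leaving out a library gave 0 to 913.

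Stricter filters changed limma's prior degrees of freedom, from 1.26 with no filter and 4.72 at 1 FPKM to 8.16 at 5 FPKM, 19.0 at 10 FPKM and 27.4 with the replicate block at 10 FPKM. In fits without a library the lone sample of its group is assumed to vary like the others. The correlation of the responses was -0.205 to 0.612 when a library was left out, reversed without E. coli replicate 1. Genes called in both responses numbered 0, 1 with the replicate block, and 0 when any library was left out. Settings added for this count gave 8 with quantile scaling, 21 with no filter, 13 at 10 FPKM or more, and 48 and 103 with the replicate block at 5 and 10 FPKM or more.

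Lists past camera for PMA against unstimulated were 14, with 7 at 5 FPKM or more, 6 to 15 when a library was left out, and 0 with an estimated correlation, with or without the replicate block. For E. coli against unstimulated they were 8, with 5 at 5 FPKM or more, 7 to 16 without a library, and 0 and 0 with an estimated correlation. For E. coli against PMA they were 17, with 6 at 5 FPKM or more, 8 with quantile scaling, 9 among genes up to 250 fragments per kb, 5 to 19 without a library, and 0 and 0 with an estimated correlation. The list settings other than the filter, pseudocount, threshold and equal medians were added after the data were seen. A background of genes with at least 1 FPKM is the filter already used. The replicate block ended 5 camera calls and added 0, and moved 44 of 87 list counts adjusted over the list alone by more than 1.5 times. Adjustment within a deposited comparison table and DESeq2, meant for other kinds of file, were not run. No named gene changed direction, while 311 single-gene values lost and 158 gained their call under an alternative. Low depth may limit all of this, since 1 fragment per kb is worth up to 1.85 FPKM, but its effect on the counts was not tested.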

Other observations

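Tests of 2 explanations, that background only dilutes PMA replicate 1 and that monocytes mark replicate 2, were set before their results were seen, and the others were chosen after. Interferon-stimulated genes differed by replicate number in each group. Their median log2 ratio of replicate 2 to replicate 1 was 1.05 in unstimulated, 2.57 in PMA and 1.77 in E. coli neutrophils, with 36, 35 and 33 of 38 members higher in replicate 2. Lists matched on mean expression had medians of 0.41, 1.73 and 0.79. The guanylate-binding protein gene GBP5 had 99.7, 21.4 and 128 FPKM in the replicate 1 libraries and 306, 365 and 337 FPKM in replicate 2. The lowest percentile among 10000 matched lists over the 3 groups was 99.95 (100 in the other groups). The list was singled out after the data were seen, however, so these percentiles are no separate evidence. Its members were also correlated (estimated correlation 0.66), which the matched lists ignore. The percentiles thus cannot decide against background or depth acting on genes of any kind. Monocyte markers reached percentiles of 90.35, 98.8 and, for PMA, 19.73. A value under 50 was set beforehand as evidence against more monocytes in the replicate 2 samples, and the PMA pair met it. That bound was set aside after the value was seen, since it was met by the PMA pair alone. In PMA replicate 1 the background estimated from olfactory receptor genes would be 44.0% of the sum. More monocytes thus stay open. Neutrophil surface receptors had median log2 ratios of 0.21, 1.88 and 0.06 in unstimulated, PMA and E. coli neutrophils. Of their 30 members, 30, 30 and 16 were higher in replicate 2. They rose less than matched lists, whose medians were 0.41, 2.44 and 0.64, at percentiles of 0.01, 0.29 and 0. A difference in cell makeup by replicate number stays open too. A difference between donors or days may be the source, which the labels cannot settle.

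PMA replicate 1 was compared with what several technical explanations predict. Low depth is argued against, since PMA replicate 2 of about equal depth correlated with the unstimulated mean better by 0.410 (95% bootstrap interval over genes 0.375 to 0.445). An evenly spread background, such as genomic DNA, may be present, since olfactory receptor genes averaged 2.91 times the highest other library (2.47 to 3.44). With that background taken off, the 200 most abundant genes still had a median ratio to PMA replicate 2 of 0.429 (0.395 to 0.457). This met the bound set beforehand as evidence against dilution alone. The genes were picked, however, on the mean of all libraries but PMA replicate 1, so PMA replicate 2 took part. Values under the background were also set to 0 before rescaling. Both steps can lower the ratio, by an amount not tested, so dilution alone stays open. That the library was not treated with PMA stays open, since of 117 genes at least 4-fold higher in PMA replicate 2 than in all libraries without PMA, 60.7% were also above those libraries in PMA replicate 1, at percentile 10.67 of matched genes (median 65.0%), and less mRNA in PMA-treated cells was not tested. On the other side, the responses of both PMA libraries against separate controls correlated at r = 0.570 across genes. Both PMA libraries share a low depth, however. The responses of PMA replicate 2 and E. coli replicate 1 also reached r = 0.440, above the E. coli pair at 0.228. Such an r thus cannot tell whether PMA replicate 1 was treated.

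The highest genes reached similar fragment densities at different depths, with a median of 637 to 843 fragments per kb over the top 20 genes in the 5 libraries other than PMA replicate 1. Removal of fragments at equal positions could set such a limit. For the 167 genes above 400 fragments per kb in both unstimulated libraries, the median log2 ratio of E. coli replicate 1 to replicate 2 was -0.0341 (-0.107 to 0.0615), where the values of 1 fragment differ by 1.21. This median met the bound set as evidence against a limit, and lay within that set as what the stimulus alone would give. A comparison with less abundant genes, made after that reading, reopened both. The 3848 genes with at least 10 FPKM and under 100 fragments per kb had -0.71, so relative to them the abundant genes stood higher by 0.68 in E. coli replicate 1. For PMA replicate 2 against unstimulated replicate 2 the abundant genes had -0.22 and the others -0.90. A smaller limit and the stimulus thus stay open. NR4A1 stood at 419.4 and 468.6 fragments per kb in E. coli replicates 1 and 2, and NR4A2 at 397.9 and 454.1. EGR2, at 251.8 and 449.8, was less alike. Whether such a limit bears on the FPKM and spread of these genes was not tested.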
